A study of Mus musculus with 6 samples.

How the data were processed

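RNA was sequenced from 6 libraries of a stable mouse cell line labelled bEND.3, a line described as brain endothelial. Of these, 3 libraries came from cells stably expressing circSlc17a5, a circular RNA named after the gene Slc17a5, and 3 from cells with an empty vector as negative control. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a SMARTer mRNA-Seq kit. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

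The authors deposited expected counts, FPKM and TPM for each gene and for each transcript. The expected counts are estimates of reads per gene that need not be whole numbers, and between 9.1% and 10.8% of the gene values of a library were not whole. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 were used, in roles that are not given in the sources used here. The FPKM values deposited by the authors are scaled by gene length and by the library total, and the TPM values deposited by the authors sum to between 999984 and 999989 in each library. Per the file headers, the authors compared the groups with DESeq2, and a further deposited table holds the log2 fold changes and the p-values and q-values of that comparison. The DESeq2 version and settings of that table, the genome build and any filters are not given in the sources used here. Of 15301 genes found in NCBI's RefSeq table of GRCm38.p6, 74.3% had the same start and end within 1 base, and gene positions are printed as the files give them.

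The gene table held 15399 genes, of which 15398 had an annotation entry and were used. All 15398 were protein coding by the table's gene type, and 0 lay on the mitochondrial chromosome. Library totals lay between 16848513 and 17600230 counts. Expected counts were rounded to whole numbers before testing. Genes kept by filterByExpr were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided, R 4.3.3) between all 3 circSlc17a5 and all 3 control libraries, with no further term. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are circSlc17a5 over control. Standard errors (SE) of edgeR fold changes were derived as the absolute log2 fold change divided by the square root of the F statistic. Normalised CPM values are counts per total count scaled by TMM. Transcripts were tested in the same way. Intervals of a ratio of summed counts are exact 95% binomial intervals, and a gene with no count in a group was compared with a floor of 3 counts over the group; both cover counting error only.

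Before the data were examined, 24 gene lists were fixed. Of these, 22 had at least 5 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists). Each was tested again with an estimated correlation and with fry. The list of mitochondrially encoded genes had 0 members in the table, and the leukocyte list had 3 tested members. Calls of members were counted at the adjusted p over all tested genes and again adjusted over the list alone. The annotation terms in the authors' table, with 10 to 300 tested genes each, were tested by a one-sided Fisher's exact test among risen and among fallen genes, with Benjamini-Hochberg adjustment over all terms and both directions of one kind. Printed terms are the first 6 per direction by p, leaving out a term that shared most of its called genes with one already printed.

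Named genes followed a rule fixed before the data were examined. It took Slc17a5, Vldlr and Qk in any case. It took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 100 counts in the higher group and with no overlap between the groups, leaving out clone and locus names. For each list it took up to 2 risen and 2 fallen members with the smallest adjusted p, or the 2 with the highest expression where no member was called. For each printed term it took the 3 called members with the smallest adjusted p. The rule named 116 genes. The examples given below are a part of these, some named genes and 1 printed term are not reported here, and genes whose call held with each library left out were preferred as examples after their values were seen. Of the 116, 29 overlap the listed span of another gene, and counting by strand is not given in the sources used here. Among the examples, Ccna2 overlaps Exosc9, Aurka overlaps Cstf1, Tcf7 overlaps Skp1, Bmp6 overlaps Txndc5, Kif20a overlaps Brd8 and Cdc23, Nusap1 overlaps Oip5, Kifc1 overlaps Smim40 and Psme1 overlaps Emc9. Dpysl2 overlaps Pnma2, Ccne2 overlaps Ints8, Zscan30 overlaps Zfp397, Rpp38 overlaps Acbd7 and Nmt2, Lmbrd2 overlaps Skp2, Zbed6 overlaps Zc3h11a, and Wipf1 overlaps a gene with a locus name. Sfn, Dhrs3, Rps6 and Ccne2 lie in the listed spans of several genes, among them Zfp984 and Zfp534. Reads of overlapping genes may not be told apart. Ribosomal protein genes have many near-identical pseudogenes and MHC class I genes have close copies, so counts of both families are uncertain to the extent that reads were split between copies.

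Alternatives fixed beforehand were DESeq2 size factors and upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom, 2 other low-count filters, stricter thresholds, each replicate left out in turn, the replicate number as a block, and limma-trend on log2(FPKM + 1), on log2(FPKM + 0.1) and with no filter. The first 2 FPKM fits used genes at 0.5 FPKM or more in at least 3 libraries. Added after the data were seen were an offset per gene and library from a spline of GC content and transcript length, and a fit of the 4 libraries other than control replicate 1 and circSlc17a5 replicate 2. Length and GC content came from GENCODE vM21 transcripts and were found for 96.6% of the genes. Lists of further cell type markers (a second endothelial list and lists of trophoblast, parietal endoderm, pluripotent cells, stratified and intestinal epithelium, hepatocytes and melanocytes) were also written after the data had been seen.

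The analysis was tested on counts simulated for this comparison from the means and library sizes of the 6 libraries. Of planted changes, edgeR recovered 72.7% of 66 genes at 1.5-fold, 86.6% of 67 at 2-fold and 100% of 63 at 4-fold among 11652 tested genes, and 5.6% of its calls were unchanged genes. At 2-fold, DESeq2 recovered 85.1% and limma-voom 86.6%. In these simulated counts libraries of a group shared no difference across genes, and the smallest planted change was 1.5-fold. Called genes in the data had a median absolute log2 fold change of 0.44. The rates of recovery and of false calls need therefore not hold for the gene calls reported here. A planted GC trend brought 34.4% of unchanged genes past the threshold without the offset and 0.1% with it, among 11645 tested genes. No trend with transcript length was planted. In the data, Spearman correlations across genes of log2 fold change were 0.4 with length and -0.22 with GC content. After the offset they were -0.0061 and -0.0099. The offset is fitted to length and GC content, so values near 0 follow from the fit and are no test of it. They cannot tell a removed bias from removed real changes that go with length or GC content. Camera called a planted list of 25 genes raised by 0.4 log2 and 0% of unchanged lists. The simulated genes varied independently of each other. In the data, the estimated correlation between members was 0.824 for cytosolic ribosomal proteins and 0.185 for G2/M and mitosis. False calls of lists with correlated members were therefore not tested. Fisher's test on the calls missed a term planted at 0.4 log2 (0% recovered); the planted effect was then raised to 1 log2, which it recovered (100%), so term tests of this kind can miss groups with weak changes.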

Results

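Gene expression was measured by RNA sequencing in mouse bEND.3 cells, as labelled, that stably expressed circSlc17a5 or an empty vector, with 3 libraries per group. Control libraries 1, 2 and 3 held 16989017, 17400258 and 17600230 counts, and circSlc17a5 libraries 1, 2 and 3 held 17004292, 17146112 and 16848513. At this depth 11722 genes were tested. The series title places circSlc17a5 downstream of VLDLR and QKI in blood vessel growth of the eye, and the comparison asks which transcripts differ when the circular RNA is expressed.

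Cells with circSlc17a5 had higher levels of 27 of 30 tested mitotic genes and of 10 of 30 genes of sterol and fatty acid synthesis, and lower levels of 15 of 37 cytosolic ribosomal protein genes. These 3 lists were called by camera with its preset correlation and not with an estimated one (adjusted p = 0.316, 0.546 and 0.546 with an estimated correlation). Transcripts of Myh15, a myosin heavy chain, were nearly absent from the control libraries and present in all circSlc17a5 libraries. Sox2, a transcription factor of stem and neural progenitor cells, was 3.97-fold higher, and Tspoap1 was 4.67-fold lower. Of the 11722 tested genes, 2584 (22%) changed by edgeR's quasi-likelihood test, with 1386 risen and 1198 fallen. Most changes were small, with a median absolute log2 fold change of 0.44 among called genes, and 200 genes rose and 62 fell by 2-fold or more. The groups did not overlap for 4994 genes (42.6%, where chance gives 10%).

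The authors' deposited table listed 2309 genes with q under 0.05, of which 1216 had risen and 1093 had fallen. Of these calls, 2127 were also made here, all 2127 with the same sign, and 164 tested genes were called only in the authors' deposited table. A further 457 genes were called only by edgeR. On FPKM values, limma-trend on log2(FPKM + 1) called 1466 risen and 697 fallen genes, a risen share of 67.8% against 53.6% from the counts. With an offset for GC content and transcript length in the edgeR fit, added after the data were seen, the balance turned to 1136 risen and 1456 fallen genes (43.8% risen). Risen genes had a median transcript length of 4512 bases and a median GC content of 48.25%. Fallen genes had medians of 2137 bases and 53.29%, and genes that were not called 3148 bases and 50.23%. The number of calls changed with single libraries, from 462 without circSlc17a5 replicate 1 to 4699 without control replicate 1. Control replicate 1 stood apart from the other control libraries. On the first principal component of log2 CPM it lay at -5.49, against -34 and -21.5 for control replicates 2 and 3. The circSlc17a5 libraries lay between 15.6 and 26.4. Across genes, control replicate 1 correlated at 0.9842 and 0.9885 with control replicates 2 and 3. With circSlc17a5 replicates 2 and 3 it correlated at 0.9871 and 0.9865, and with circSlc17a5 replicate 1 at 0.9832.

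Slc17a5, the host gene of the circular RNA and a transporter that exports sialic acid from lysosomes (Entrez 235504, chromosome 9, 78536487 to 78588045, minus strand), was 1.36-fold higher with circSlc17a5. Its counts were 391, 358 and 380 in the control libraries and 605, 495 and 492 in the circSlc17a5 libraries. The normalised level was 22.3 ± 0.65 CPM in control and 30.3 ± 3.01 in circSlc17a5 cells (SD, n = 3 libraries each). The log2 fold change was 0.44 with a standard error of 0.093 (edgeR adjusted p = 0.0133). This call ended without control replicate 3 (adjusted p = 0.0527) or without circSlc17a5 replicate 1 (adjusted p = 0.0608). These are counts per gene, which may or may not include reads of the circular RNA, and circSlc17a5 itself was not measured separately. Of the other genes in the series title, Vldlr, a lipoprotein receptor (Entrez 22359, chromosome 19, 27216480 to 27254231), had a log2 fold change of 0.22 (SE 0.108, adjusted p = 0.153). Qk, the gene of the RNA-binding protein QKI (Entrez 19317, chromosome 17, 10202604 to 10319361), had one of 0.28 (SE 0.104, adjusted p = 0.0753), so neither passed the test. With the offset their log2 fold changes were 0.03 and 0.08.

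**Figure D1:**
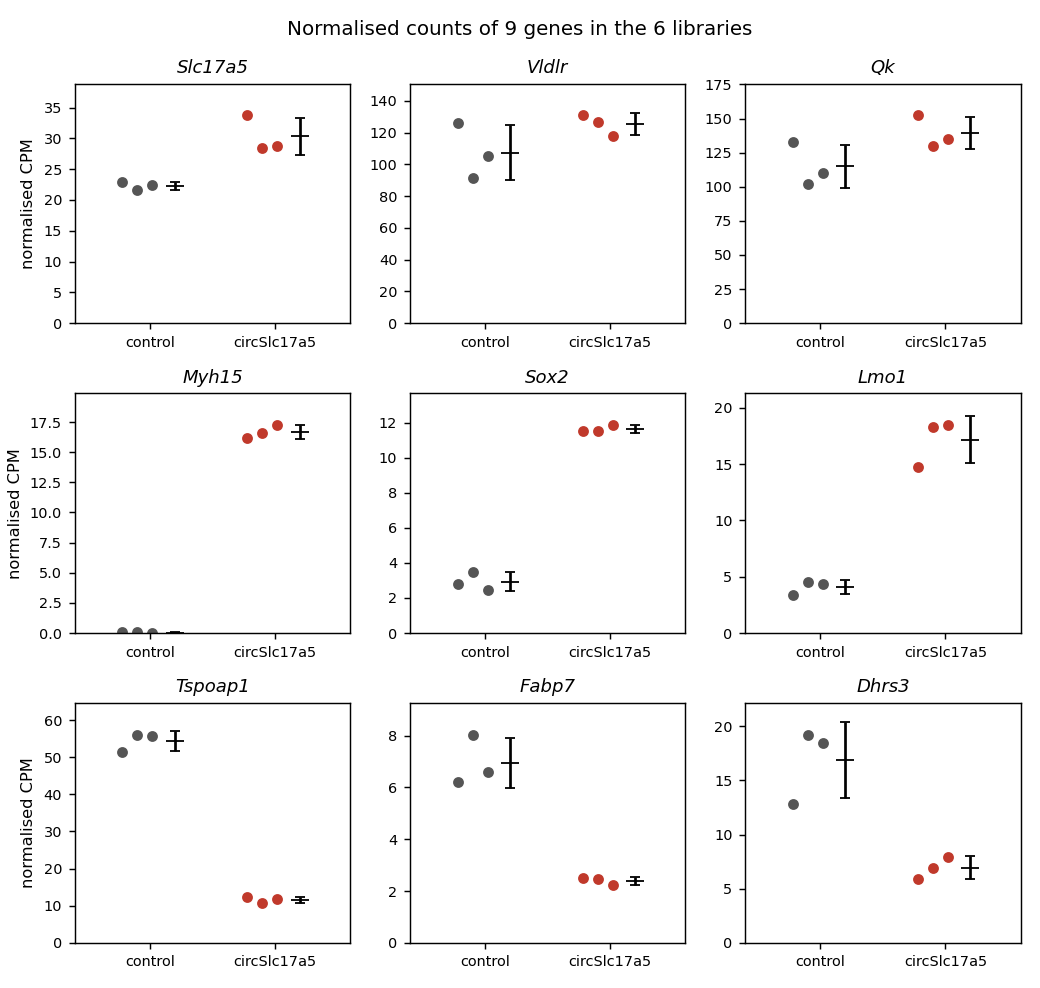
Normalised CPM (vertical axes, from 0) of 9 genes in the 3 control and 3 circSlc17a5 libraries, 1 point per library, with the mean and SD of each group beside the points. Slc17a5, Myh15, Sox2 and Lmo1 were higher and Tspoap1, Fabp7 and Dhrs3 lower in every circSlc17a5 library than in every control library, while the groups of Vldlr and Qk overlapped.

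Myh15 (chromosome 16, 49057400 to 49199563) had 1, 1 and 0 counts in the control libraries and 289, 289 and 295 with circSlc17a5, a ratio of 421 with an exact 95% interval from 116 to 3480. Lmo1, a transcriptional cofactor, was 4.21-fold higher (adjusted p = 6.06e-05) and Sox2 3.97-fold (adjusted p = 6.06e-05). Rab15 was 4.14-fold, Wipf1 3.88-fold and the neuronal amino acid transporter gene Slc6a17 3.88-fold higher. The rises of Zbed6, Lmbrd2 and Tnks were uneven between libraries. Their calls ended without control replicate 3, and those of Zbed6 and Lmbrd2 also without circSlc17a5 replicate 1, with highest adjusted p values of 0.0908 for Zbed6, 0.0611 for Lmbrd2 and 0.057 for Tnks. Zbed6, which lies inside the span of Zc3h11a, was also not called by the DESeq2 Wald test.

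Tspoap1 (chromosome 11, 87758194 to 87785928) fell from 54.3 ± 2.67 to 11.6 ± 0.81 normalised CPM (SD, n = 3 libraries each; edgeR adjusted p = 4.60e-07). Fabp7, a fatty acid binding protein of neural progenitors, was 2.89-fold lower (adjusted p = 6.30e-04), and Dhrs3, which reduces retinal, 2.43-fold lower (adjusted p = 0.00174). The calcium-binding protein gene Cabp1 was 2.97-fold, Sfn 2.65-fold, Dpysl2 2.45-fold and the MHC class I gene H2-T24 2.39-fold lower. Falls of Zscan30, Rpp38 and Rpl23 were called with all 6 libraries and lost with some left out. The call of Zscan30 ended without control replicate 2 or 3 or circSlc17a5 replicate 1 or 2 (highest adjusted p = 0.077). That of Rpp38 ended without circSlc17a5 replicate 1, 2 or 3 (highest adjusted p = 0.0928), and that of Rpl23 without control replicate 3 or circSlc17a5 replicate 1 (highest adjusted p = 0.0688).

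Among 30 tested genes of G2/M and mitosis, 27 rose, 0 fell and 3 were not called, and 28 rose adjusted over the list alone. Their median log2 fold change was 0.48 (camera adjusted p = 1.05e-18; adjusted p = 0.316 with an estimated correlation). Ccna2, which encodes cyclin A2, rose by 0.63 on the log2 scale and Aurka, a kinase of the mitotic spindle, by 0.68. Of 30 S phase genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.136), among them the origin licensing factor Cdt1 at 1.49-fold and Ccne2 at 2.88-fold. Of 22 tested p53 targets, 6 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.138), with Pmaip1 at 1.89-fold and Ephx1 at 1.95-fold.

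Of 30 genes of sterol and fatty acid synthesis, 10 rose, 1 fell and 19 were not called, and 13 rose and 1 fell adjusted over the list alone. The list was called higher, with a median log2 fold change of 0.17 (camera adjusted p = 0.0107; adjusted p = 0.546 with an estimated correlation). Srebf2, the master regulator of sterol synthesis, was 1.34-fold higher. The call of Srebf2 ended without circSlc17a5 replicate 1 (adjusted p = 0.0501).

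Of 37 cytosolic ribosomal protein genes, 15 fell, 0 rose and 22 were not called, and 23 fell adjusted over the list alone. The list was called lower, with a median log2 fold change of -0.31 (camera adjusted p = 1.67e-09; adjusted p = 0.546 with an estimated correlation). With the offset for GC content and transcript length, added after the data were seen, the median was -0.15 and 13 members fell (adjusted p = 9.67e-04). The number called was 6 on FPKM values (median -0.23), 23 by DESeq2 and 24 without control replicate 1 and circSlc17a5 replicate 2 (median -0.43). Rpl7 fell by 0.58 on the log2 scale (adjusted p = 0.00689). Rps6 fell by 0.67 (adjusted p = 0.0113), a call that ended without control replicate 3 or without circSlc17a5 replicate 1 (highest adjusted p = 0.0611). With an estimated correlation 0 lists were called by camera and 1 had an unadjusted p under 0.05, while directional fry called 6. Fry called the G2/M list (adjusted p = 0.00975) and the sterol list (adjusted p = 0.0348) and not the ribosomal list (directional adjusted p = 0.146, mixed 0.0509). Other splits of the 6 libraries, which mix the groups, gave between 1 and 6 called lists against 3 for the real groups.

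**Figure D2:**
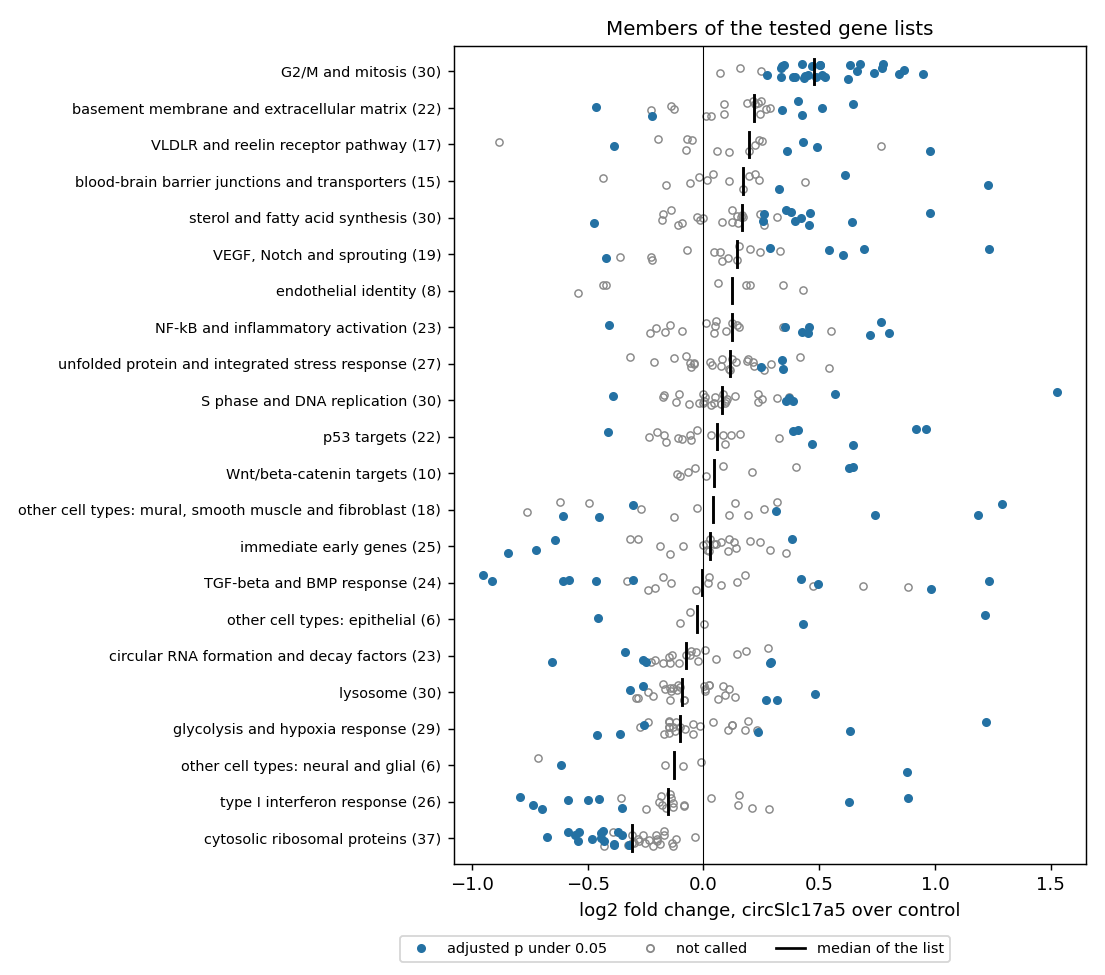
Log2 fold change (horizontal axis, circSlc17a5 over control) of each tested member of the 22 tested gene lists, with the number of tested members in parentheses. Filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians, from 0.48 for G2/M and mitosis to -0.31 for cytosolic ribosomal proteins.

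The other lists were not called by camera with all 6 libraries and no offset. With the offset for GC content and length 6 of them were called, S phase (adjusted p = 0.0483), NF-kB (0.0199), the unfolded protein response (9.67e-04) and p53 targets (0.024) as higher, and interferon (0.024) and circular RNA factors (0.0198) as lower. Directional fry called VEGF (adjusted p = 0.0413), Wnt targets (0.0147) and S phase (0.0243) as higher and interferon (0.0147) as lower. Without control replicate 1, 5 more lists passed, namely blood-brain barrier (adjusted p = 0.0338), interferon (0.0477), NF-kB (0.0267), basement membrane (0.0477) and the unfolded protein response (0.0231). Of 8 tested genes of endothelial identity, 0 rose and 0 fell by edgeR, also adjusted over the list alone (adjusted p = 0.892). An unadjusted p under 0.05 was found for 3, and DESeq2 and limma-voom called 0. In the fit without control replicate 1 and circSlc17a5 replicate 2, 1 of 9 tested rose and 2 fell. With the offset Mef2c was lower (log2 fold change -0.71, adjusted p = 0.0194; named after its values were seen). The tested members with the highest CPM, Flt1 and Ets1, had log2 fold changes of 0.20 (adjusted p = 0.125) and 0.19 (adjusted p = 0.153), and of -0.01 and 0.04 with the offset. In the list of VEGF, Notch and sprouting, 5 of 19 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.136). Nrp2, a co-receptor of VEGF, was 1.52-fold and the receptor gene Notch1 1.46-fold higher, and with the offset their log2 fold changes went from 0.61 to 0.40 and from 0.54 to 0.28, both still called. Of 10 Wnt targets 2 rose and 0 fell, both also adjusted over the list alone (adjusted p = 0.21), including Tcf7 at 1.56-fold. Of 15 blood-brain barrier genes 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.136), including the tight junction gene Ocln at 2.34-fold. In that list 2 rose and 1 fell with the offset, and 7 rose and 1 fell in the fit without control replicate 1 and circSlc17a5 replicate 2. Of 17 genes of the VLDLR and reelin pathway, 4 rose and 1 fell (5 and 2 adjusted over the list alone; adjusted p = 0.136), with the adaptor gene Crk at 1.35-fold. With the offset 2 rose and 2 fell, and the median log2 fold change went from 0.20 to 0.03.

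In the type I interferon list 2 of 26 rose and 7 fell, with the same counts adjusted over the list alone (adjusted p = 0.0534). Usp18, an inhibitor of interferon signalling, was 1.62-fold lower. The list also passed the threshold without control replicate 2 (adjusted p = 0.018) and without circSlc17a5 replicate 1 (adjusted p = 0.0235). Of 23 genes of NF-kB and inflammatory activation, 7 rose and 1 fell, as they did adjusted over the list alone (adjusted p = 0.112), among them the chemokine genes Ccl7 at 1.74-fold and Ccl2 at 1.65-fold. Of 25 immediate early genes 1 rose and 3 fell, with equal counts adjusted over the list alone (adjusted p = 0.695); Rhob was 1.56-fold and Klf2 1.65-fold lower. With the offset 3 rose and 3 fell, and the direction of the list test turned from lower to higher (adjusted p = 0.64). Of 24 genes of the TGF-beta and BMP response 4 rose and 6 fell (4 and 7 adjusted over the list alone; adjusted p = 0.602), with Bmp6 1.98-fold higher and Atoh8 1.94-fold lower. The balance in this list turned on FPKM values, with 4 of 21 risen and 3 fallen, and was 4 and 8 with the offset. In the basement membrane and matrix list 5 of 22 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.138), but with the offset 2 rose and 3 fell, and the median log2 fold change went from 0.22 to 0.01. Without control replicate 1 and circSlc17a5 replicate 2, 10 of 21 rose (median 0.28), and on FPKM values 6 of 22 rose (median 0.26). Its member Thbs1 was 1.56-fold higher, a call that ended without control replicate 3 or without circSlc17a5 replicate 1 (highest adjusted p = 0.0589).

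Of 29 genes of glycolysis and hypoxia 3 rose and 3 fell, also adjusted over the list alone (4 and 2 on FPKM values, 3 and 4 with the offset; adjusted p = 0.423), with Pfkfb3, a regulator of glycolysis, 1.55-fold higher. The unfolded protein and stress list had 3 of 27 risen and 0 fallen by edgeR, also adjusted over the list alone (adjusted p = 0.136). In it 6 rose on FPKM values and 7 without control replicate 1 and circSlc17a5 replicate 2, and DESeq2 called 7. The lysosome list had 3 of 30 risen and 2 fallen (3 and 1 adjusted over the list alone; adjusted p = 0.353), or 2 risen and 3 fallen with the offset and 3 risen and 7 fallen without control replicate 1 and circSlc17a5 replicate 2 (9 called by DESeq2), with Scarb2 at 1.40-fold. Of 23 factors of circular RNA formation and decay, 2 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.257). With the offset 6 of these fell, and the median log2 fold change went from -0.07 to -0.20 (adjusted p = 0.0198). Without control replicate 1 and circSlc17a5 replicate 2, 3 rose and 3 fell, and on FPKM values 1 rose and 2 fell. Ddx39b, an RNA helicase of mRNA export, was 1.57-fold lower.

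Markers of other cell types moved in both directions. Of 18 tested genes of mural cells, smooth muscle and fibroblasts 4 rose and 3 fell (adjusted p = 0.602), with Notch3 2.45-fold and Pdgfrb 2.27-fold higher and Anpep 1.37-fold lower. Notch3 and Pdgfrb were low, with mean FPKM values of 0.27 and 0.53 over the 6 libraries against 103 for Anpep. Of 6 epithelial genes 2 rose and 1 fell (adjusted p = 0.833), and of 6 neural and glial genes 1 rose and 1 fell (adjusted p = 0.576). These counts were the same adjusted over each list alone. Median and mean log2 fold change differed in sign for the endothelial identity (0.125 and -0.02), immediate early (0.03 and -0.04), TGF-beta (-0.01 and 0.03) and epithelial lists (-0.03 and 0.17), none of them called. Of 3 tested leukocyte genes 0 passed edgeR's test, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05. With the offset Cd68 of this list was called (log2 fold change 0.38, edgeR adjusted p = 0.0116). Some collagen and smooth muscle genes were high in control replicate 1 and circSlc17a5 replicate 2 and others were not: Col1a2 had 508, 3 and 0 counts in control and 7, 257 and 77 in circSlc17a5 libraries, while Col3a1 had 5640, 5056 and 4715 in control and 6113, 5938 and 5482 in circSlc17a5 libraries (named after their values were seen). Krt8, Krt18 and Krt19, keratins of simple epithelia, had mean FPKM values of 403, 1000 and 384 over the 6 libraries. The endothelial genes Pecam1 and Cdh5 had 0.172 and 0.398, and Kdr, the main VEGF receptor gene, had between 0 and 5 counts per library. Other genes of the endothelial list were higher, with 13.7 for Egfl7, 10.2 for Plvap, 8.71 for Flt1 and 8.43 for Ets1. The epithelial genes Epcam and Cdh1 had mean FPKM values of 0.858 and 0.0183.

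**Figure D3:**
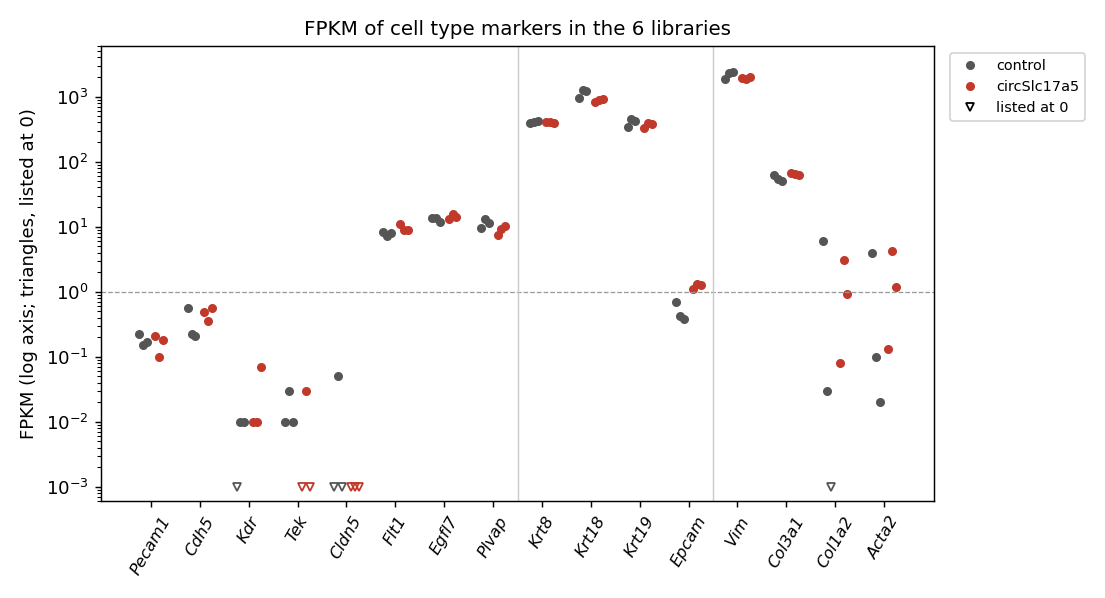
FPKM (vertical log axis) of 16 marker genes in the 3 control and 3 circSlc17a5 libraries, 1 point per library, with triangles for values listed at 0 and a dashed line at 1 FPKM. From left to right stand endothelial, epithelial and mesenchymal markers; Pecam1 and Cdh5 lie under 1 FPKM in all 6 libraries, and Krt8, Krt18 and Krt19 lie above 300.

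Of 4324 annotation terms, 52 were over-represented among risen and 78 among fallen genes by Fisher's exact test. Risen genes included 17 of 31 tested genes of mitotic sister chromatid segregation (adjusted p = 3.41e-05), such as Nusap1, Sgo2a and Espl1, 38 of 124 of the kinetochore (adjusted p = 1.44e-05), such as Bub1 and Cenpf, and 44 of 183 of the spindle (adjusted p = 4.01e-04), such as Dlgap5. They also included 19 of 45 genes of the kinesin complex (adjusted p = 7.75e-05), with Kif20a 1.67-fold and Kifc1 1.41-fold higher. Golgi and Golgi-to-ER traffic held 41 of 162 (adjusted p = 1.88e-04), with Scoc at 1.53-fold. Its other leading members were kinesin genes, Kif20a among them.

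Fallen genes included 44 of 169 genes of rRNA processing (adjusted p = 1.52e-06), such as Wdr46 and Rpl7, and 50 of 218 of translation (adjusted p = 9.36e-06), such as the initiation factor gene Eif1ax at 1.34-fold lower. They included 24 of 81 genes of a set on mRNA stability and AU-rich elements (adjusted p = 1.13e-04), whose leading members were the small heat shock protein gene Hspb1 at 1.77-fold lower (log2 fold change -0.83, and -0.54 with the offset) and the proteasome genes Psmb8 and Psme1 at 1.63-fold and 1.61-fold lower. The spliceosome held 31 fallen of 127 genes (adjusted p = 0.00128), led by Ddx39b. Large ribosomal subunit biogenesis held 12 of 30 (adjusted p = 0.0098) and TFIID complex binding 6 of 11 (adjusted p = 0.0447), and with the offset for GC content and length these had adjusted p values of 0.238 and 0.975. The other terms given here passed Fisher's exact test with the offset too. The adjusted p rose to 0.0297 for translation, 0.0151 for the mRNA stability set, 0.0149 for Golgi traffic and 0.00553 for the spliceosome. It rose to 3.91e-04 for rRNA processing, 6.45e-04 for sister chromatid segregation and 1.68e-04 for the kinetochore. For the kinesin complex (6.18e-05) and the spindle (1.03e-04) it fell. With genes changed by 2-fold or more as calls, 15 terms passed and none of the terms printed here did.

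At the level of transcripts, 28266 were tested and 2 changed by edgeR, 1 of Nxf7 (log2 fold change 1.82, SE 0.069, adjusted p = 0.0153) and 1 of Cfl2, which encodes cofilin 2 (1.13, SE 0.059, adjusted p = 0.044); both genes were called at gene level. Nxf7 and Cfl2 were not fixed beforehand and are named because the count is small. An unadjusted p under 0.05 was found for 4160 transcripts, and the DESeq2 Wald test called 2127 transcripts. Without control replicate 1 edgeR called 32 transcripts, and with any other single library left out it called 0 (between 2688 and 3520 at an unadjusted p under 0.05). The most abundant transcript of Slc17a5 had 389, 176 and 380 counts in control and 558, 447 and 492 in circSlc17a5 libraries (log2 fold change 0.61, SE 0.312, edgeR adjusted p = 0.436). In control replicate 2, 88.3 and 91.9 counts were assigned to other transcripts of the gene, which had 0 in control replicates 1 and 3. The fold change of the most abundant transcript thus depends on how reads were split between isoforms.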

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

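The offset for GC content and length and the fit of 4 libraries were chosen after the data were seen; all other settings were fixed before. The number of calls, 2584 in the reported fit, stayed between 2534 and 2604 with other scaling factors, DESeq2, limma-voom or other low-count filters. Of the 2584 reported calls, these fits kept between 2275 (DESeq2 Wald test) and 2566 (DESeq2 size factors) with the same sign. With single replicates left out, calls ranged from 462 to 4699 (risen 346 to 2424, fallen 116 to 2275), called transcripts from 0 (2688 to 3520 at an unadjusted p under 0.05) to 32 and called lists from 3 to 8; the lowest gene count was without circSlc17a5 replicate 1 and the highest of each without control replicate 1. The 2-fold threshold left 262 genes (200 risen, 62 fallen) and an adjusted p under 0.01 left 435 (320 and 115). Limma-trend on FPKM called 697 fallen genes with a pseudocount of 1, 674 with 0.1, and 922 genes (667 risen, 255 fallen) with no filter. The offset gave 2592 calls (1136 risen, 1456 fallen), turning the balance of 1386 risen and 1198 fallen, and kept 1858 of the reported ones; the 4 libraries gave 3680 calls (1951 risen, 1729 fallen). Transcript calls were 2127 by DESeq2 and 1 with no filter. Slc17a5 had log2 fold changes from 0.358 to 0.488 with single replicates left out. At the 0.05 threshold it passed in these fits, and in all other fits listed here, except without control replicate 3 (log2 fold change 0.45) and without circSlc17a5 replicate 1 (0.36). Called lists were 0 with an estimated correlation, 6 by directional and 20 by mixed fry, 9 with the offset and 7 with the 4 libraries. Called terms were 197 by DESeq2, 15 at 2-fold and 72 with the offset. With the offset 41 were among risen and 31 among fallen genes, against 52 and 78 without it. The cause of these moves was not tested. Of the 110 named genes that were called, 61 were called with each replicate left out and 49 were not, 9 lost their call with the offset and 8 by DESeq2.

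The replicate numbers were not taken to pair the samples, since no label says that they mark a shared culture or day. Between the groups, deviations of same-numbered libraries correlated across genes at 0.22, 0.07 and 0.06. Those of libraries with different numbers correlated at between -0.31 and 0.31. Control replicate 1 correlated best with circSlc17a5 replicate 1 (0.22), and control replicate 2 with circSlc17a5 replicate 3 (0.31). These values leave open whether the samples are paired. With the replicate block, calls were 4429 (2324 risen, 2105 fallen), transcripts 0 (3913 at an unadjusted p under 0.05) and terms 238; TFIID complex binding then had an adjusted p of 0.0671, and no list call changed. Block and offset together gave 1620 risen and 2064 fallen genes. Depth limits genes with few counts; 9395 genes had 100 or more counts in every library.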

Other observations

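The tests of cell identity, of sequencing depth, of a response in the collagen pattern and of a single second population were chosen after their results had been seen, as were all genes named here outside the fixed rule. The marker lists were also written after values of some of their members had been seen, and the second endothelial list shares 1 gene, Nos3, with the fixed one, so they are not independent evidence. The tests of GC content with length and of a gradient were prompted by a principal component plot; their values had not been seen.

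Some genes of antigen processing by the immunoproteasome, picked after their values were seen and not as a fixed list, were lower with circSlc17a5. Psmb8 fell by 0.71, Psmb10 by 0.45, Psme1 by 0.69, Psme2 by 0.45, Psmb9 by 0.49 and the peptide transporter gene Tap2 by 0.45 on the log2 scale, and the call of Psmb9 ended with the offset for GC content and length (log2 fold change -0.33, edgeR adjusted p = 0.0788). Tap1, the partner of Tap2, did not pass the test (log2 fold change -0.21, adjusted p = 0.128). With the offset Psmb10 and Psme2 fell by 0.27 and 0.28. The MHC class I gene H2-T24 fell by 1.26 (adjusted p = 0.0101), while the classical class I genes H2-K1 and H2-D1 did not pass the test, with log2 fold changes of -0.07 and 0.04, and 0.08 and 0.14 with the offset. Their partner B2m had 0.13 (adjusted p = 0.556, 0.724 and 0.301 for H2-K1, H2-D1 and B2m). Of 42 tested genes of the KEGG proteasome pathway, 15 fell (Fisher's exact test, adjusted p = 0.0023), a call that ended with the offset (14 fell, adjusted p = 0.0588), while 17 of 58 genes of the proteasome complex fell with and without it (adjusted p = 0.0376 and 0.00314). After the offset, windows of 25 neighbouring tested genes shifted most on chromosome 17 (lowest window median -0.32). Their central genes start between 34204479 (Tap2) and 34647146. Psmb8, Psmb9 and Tap1 lie beside Tap2 and inside the window around it, so their values enter its median.

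Of 102 tested genes of axon guidance, 29 rose (Fisher's exact test, adjusted p = 0.00439; 26 with the offset, adjusted p = 0.00392). The potassium channel gene Kcnab1 had 0 counts in control and 23, 23 and 24 with circSlc17a5, at least 22.5-fold higher against a floor of 3 counts over the group. Scn9a, a sodium channel gene, had a ratio of 51.2 (exact 95% interval 13.8 to 428). Sox2 rose, while Esrrb, another factor of stem cells, had 45, 54 and 67 counts in control and 12, 8 and 10 with circSlc17a5 (log2 fold change -2.51, adjusted p = 5.99e-04).

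The many small changes between the groups may in part follow a technical difference of the libraries. A bias by GC content and transcript length as the whole cause is argued against by the offset, after which 71.9% of the called genes were still called with the same sign. Gains or losses of long chromosome stretches as the main cause are argued against too. For 0.5% of called genes the window of 25 tested neighbours around the gene was shifted (at most 0.7% in 100 shuffled orders). A window counted as shifted with a median log2 fold change at least 0.2 from 0 after the offset. Stretches much shorter than a window may be missed, since a median can leave them out. A gradient that also runs within the groups stays open, since fold changes within and between groups that share no library correlated across genes at up to 0.54 for the control group and 0.22 for the circSlc17a5 group. The 10 splits of 6 libraries are too few for a share under 0.05: 1 of the 10 gave as many called genes (2584, highest other 0, with 22 to 1542 at an unadjusted p under 0.05), 1 as many transcripts (2, highest other 0, with 253 to 1518) and 9 as many lists (3, highest other 6), and clonal differences between the stable lines and a response to circSlc17a5 remain open, as untested.

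Low endothelial markers with high keratins in all 6 libraries are consistent with cells of another identity than the label. Of 23 listed genes of a second endothelial list, 30.4% reached 1 FPKM (Ecscr, at 141 FPKM, the most abundant), against 20% of the 20 listed genes of the fixed endothelial list. Too few reads are argued against, since at 1 FPKM 0% of 42 listed genes of both endothelial lists would have under 10 counts per library (fewest 13.7). Shares at 1 FPKM were 77.8% of 9 listed genes for parietal endoderm (Sparc at 446 FPKM, 4 of them also in the fixed basement membrane list), 62.5% for mural cells and fibroblasts, 50% of 2 for hepatocytes, 45.5% for trophoblast (Rhox5 at 690 FPKM), 41.7% for epithelium, 37.5% for intestine, 36.4% for neural cells, 33.3% each for pluripotent cells and melanocytes, 28.6% for stratified epithelium and 25% for leukocytes. Unlisted members were left out of these shares. Listed were 23 of 28 members of the second endothelial list, 20 of 27 of the fixed one and 9 of 12 for parietal endoderm. For mural cells 24 of 26 were listed, for trophoblast 11 of 16, for epithelium 12 of 15 and for intestine 8 of 10. For neural cells it was 11 of 16, for leukocytes 12 of 19 and for stratified epithelium 7 of 10. For pluripotent cells it was 6 of 12, for melanocytes 3 of 7 and for hepatocytes 2 of 8. No cell type can be named from the shares, and loss of endothelial expression by the labelled line stays open, as no test here separates it from another identity.

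Some collagen and smooth muscle genes, but not Col3a1 or Des, were high in single libraries of both groups, with Tagln at 139, 2 and 0 counts in control and 7, 147 and 20 in circSlc17a5 libraries, and Col5a2 at 133, 0 and 0 and 3, 78 and 16. The pattern was taken as the 11 genes with at least 20 counts in control replicate 1 and at most 2 in the other control libraries, which leaves out Col1a2 and Acta2 and takes in genes of neither kind, such as App, Itgb1 and Gm2007. RNA of a second cell population stays open: the 11 genes did not keep 1 ratio between control replicate 1 and circSlc17a5 replicate 2 (chi-square p = 6.37e-19), but this sets single libraries against counting error alone and so excludes neither a population of fixed composition nor one that differs between libraries. For 10 of the 11 genes, all but Zfp973, control replicate 1 was higher than circSlc17a5 replicates 1 and 3. A response to circSlc17a5 was to be excluded only if none of the 11 was called. Zfp973 was called (26, 0 and 0 against 140, 62 and 34 counts, edgeR adjusted p = 0.0281). Itgb1, Gm2007, Mmp2, App, Col14a1 and Lum were not kept by the low-count filter and so could not be called. A response may hold for Zfp973 and stays open. For the other genes the high control values rest on control replicate 1 alone, so a response is not excluded for them either.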
